A study of Aliger gigas with 7 samples.

How the data were processed

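Ovary RNA of 7 wild adult queen conchs, a large marine snail of the Caribbean and Florida, was measured on single-colour oligonucleotide arrays, 1 array per animal. Per the labels' protocols, 1 ug of total RNA from each animal was labelled with the dye Cy3. The arrays were read with Agilent Feature Extraction, per the submitters' processing notes, and its version is not given in the sources used here.

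The table deposited by the authors holds 1 log2 value per gene title and array, for 4328 gene titles and 7 arrays. The log base is not stated. It was read as 2 from the range of the values, from 0.27 to 17.53, and every fold change below rests on that reading. The 7 columns have nearly equal means, so the values were taken as already normalized between arrays by the authors. The normalization, the treatment of background and the way in which several probes of a title were condensed to 1 value are not given in the sources used here. A title is the name of a protein or gene that the authors attached to the conch sequence, often from a vertebrate, an insect or a plant. How the titles were assigned is not given in the sources used here, so a title names the closest match and not an established conch orthologue. Several titles can stand for 1 gene, and a title can join several names.

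Animals were grouped by the location in the labels, 4 offshore and 3 nearshore, and are named by the codes in the sample titles (OF1 to OF4, NF1, NF3 and NM3). The series design makes offshore the reference, so a positive log2 fold change means a higher value nearshore. All 7 sample columns of the table were used, and 4275 titles have all 7 values. Another 53 titles lack 1 value, 45 of them on array NM3, and were tested on the values present in the per-title fit. They were left out of distances, principal components and gene list tests. No filter was applied to dim titles. The table carries no detection calls, background signals or scanner flags, so it is not known which low values lie above background. The number of arrays limits the precision.

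Each title was tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values and group as the term. The two-sided p-values were adjusted with the method of Benjamini and Hochberg over all 4328 titles. A title is said to have risen, fallen or changed where its adjusted p was under 0.05. SE is the moderated standard error of the log2 fold change. Whole profiles were compared with an exact permutation test over the 35 splits of the 7 arrays into 4 and 3. Its statistic is the mean Euclidean distance between groups minus the mean distance within groups, tested one-sided. The smallest p this test can give is 0.0286.

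Before the data were examined, 19 gene lists were fixed as search patterns on the titles. They cover egg yolk, oocyte maturation, germ cells, sperm and axoneme, steroids, xenobiotic metabolism, stress, cytosolic ribosomal proteins, oxidative phosphorylation, the proteasome, lysosome and cell death, DNA replication, histones and tubulins. They also cover tissues that a gonad dissection can hold: muscle, extracellular matrix, digestive gland, haemocytes and nerve. Lists with at least 5 titles were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 17 lists tested. Fisher's exact test of the number of members that rose or fell, against all titles, was added after the data were seen, with adjustment over its 34 tests. A pattern also catches titles that share a word but name another kind of protein. There were 61 such matches, picked by name after the matches were seen, and the tests were repeated without them.

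The titles named below follow a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among changed titles whose name identifies a protein, 1 title per name, and up to 4 members with the smallest p from each gene list. Of the 400 changed titles, 128 that rose and 167 that fell have such a name. Any other title named was chosen after its values were seen, and is said to be.

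The alternatives were quantile normalization, median centring, leaving out the 25% of titles with the lowest mean, array weights, leaving out each array in turn, a mean-dependent prior without and with robust estimation, an ordinary pooled-variance test, other thresholds, titles of 1 name averaged, camera with an estimated correlation, fry, and a rank-based distance. Cyclic loess normalization and the lists without stray titles were added after the data were seen. The per-title and list tests were tested on simulated data for 4275 titles with 200 changed, in 20 runs. With 4 arrays against 3, the per-title test recovered 12.1% of titles changed by 1 on the log2 scale, 53.8% of those changed by 2 and 80.6% of those changed by 3. On average 5.70% of its calls were false. The list test called a list in 1 of 20 runs without a shifted list, and called a list of 40 titles shifted by 1 in 20 of 20. The simulated titles were uncorrelated, so real lists are harder to judge. Both groups were simulated with the same spread per title. In the real data nearshore arrays were less alike (mean Pearson's correlation 0.948) than offshore arrays (0.965). The share of false calls in the real data may therefore differ. In the simulation changes below about 4-fold were often missed. The real data held 400 calls, more than the 200 titles changed there, so recovery in the real data may differ. Figures were drawn with matplotlib 3.10.9.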

Results

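Gene expression was measured in the ovaries of 7 mature queen conchs from the Florida Keys. Conchs of the offshore site, Pelican Shoal, reproduce normally, and 4 females from there (OF1 to OF4) formed the reference group. Conchs of the nearshore site, Tingler Island, show impaired reproduction, and 3 animals came from there. Of these, NF1 and NF3 were labelled normal females, and NM3 was labelled an apparent imposex female, a female bearing male sexual characters. Each array held the RNA of 1 animal. The arrays had nearly equal mean log2 signals, from 5.83 in NM3 to 5.89 in OF4. NM3 lacked a value for 45 of the 4328 gene titles, whereas each of the other arrays lacked at most 3. The median level of the titles missing in NM3 was 11.14, against 5.17 for all titles. Each group came from 1 place, and the sources used here name no extraction, slide or scan batch, so the comparison is between these 2 collections of animals.

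The first comparison asked which genes differed between the ovaries of the nearshore and the offshore animals. The 12 largest rises nearshore included titles for a Rac activator, F-box proteins, a protocadherin and a fibrillar collagen, and the 12 largest falls included titles for a mitochondrial transporter, a cell cycle kinase and cytochromes P450 of family 3A. T-cell Lymphoma Invasion And Metastasis 1, an activator of the small GTPase Rac, rose from 6.65 ± 1.27 (SD, n = 4) offshore to 12.14 ± 2.56 (n = 3) nearshore, a log2 fold change of 5.49 (SE 1.20, adjusted p = 0.0367). NM3 was at 14.92, NF3 at 11.64 and NF1 at 9.87, and T-cell Lymphoma Invasion And Metastasis 1 passed in 2 of the 7 fits without 1 array, with changes from 4.10 to 6.63 over the alternatives. Sideroflexin 1, a serine transporter of the mitochondrial membrane, fell from 7.89 ± 0.40 to 3.33 ± 1.58, a change of -4.56 (SE 0.68, adjusted p = 0.0173), and passed in 4 of these 7 fits. In all, 400 of 4328 titles (9.24%) changed at an adjusted p under 0.05 in limma, 169 of them higher and 231 lower nearshore. The changes called ranged in size from 0.92 upward on the log2 scale, with a median size of 1.70.

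Among the other large rises, Fibrinogen C Domain Containing 1, a member of a family of recognition proteins, rose by 4.73 (SE 0.61, adjusted p = 0.0128). F-box Protein 32, a substrate-binding subunit of a ubiquitin ligase known from wasting muscle, rose by 4.18 (SE 0.56), and F-box Protein 25 by 3.82 (SE 0.46). Of the 8 titles with F-box in the name, counted after the data were seen, the other 6 did not pass, and the median was -0.18. Protocadherin 1, a cell adhesion protein, rose by 4.11 (SE 0.89), with NF1 at 9.19, NF3 at 6.08 and NM3 at 5.59, and by 2.99 without NF1. A title named after the plant cytochrome P450 CYP76C1 rose by 3.60 (SE 0.53). Eukaryotic Translation Initiation Factor 1A, Y-linked, whose title comes from a vertebrate match and says nothing of a Y chromosome in conchs, rose by 3.43 (SE 0.39), with only 2 nearshore values because NM3 lacked it. Collagen, Type I, Alpha 1 was already bright offshore, at 12.52 ± 0.49, and rose to 15.72 ± 0.35. The remaining titles of the 12 largest rises were Tropomyosin 1, Copper Transporter 1C, the LIM protein Cysteine-rich Protein 1 and a mitochondrial carnitine/acylcarnitine carrier, which rose by 2.89, 2.86, 2.63 and 2.49.

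Cell Division Cycle 2, the kinase that drives entry into M phase in meiosis and mitosis, fell by 4.29 on the log2 scale (SE 0.87, adjusted p = 0.0304), from 7.53 ± 0.44 offshore to 3.24 ± 2.07 nearshore. Its nearshore values ran from 1.44 to 5.50. The call held in 2 of the 7 fits without 1 array, and the change ran from -5.42 to -3.39 over the alternatives. Origin Recognition Complex, Subunit 1-like, which marks sites where DNA replication starts, fell by 2.85 (SE 0.44). The title Cytochrome P450, Family 3, Subfamily A, Polypeptide 5 fell by 3.43 (SE 0.83), with NF1 at 3.46, NF3 at 6.65 and NM3 at 7.04, and by 2.30 without NF1. Polypeptide 65 of the same subfamily fell by 2.76 (SE 0.53). These enzymes oxidize steroids and foreign compounds in vertebrates. The 2 titles had nearly the same values on most arrays, such as 9.73 and 9.71 in OF4 and 7.04 and 7.08 in NM3. In NF1 they differed, at 3.46 and 5.04. Whether they stand for 1 conch gene or for 2 is not known. Among metabolic enzymes, Farnesyl Diphosphate Synthase, which makes precursors of sterols and other isoprenoids, fell by 3.02 (SE 0.30). Adenylosuccinate Synthetase, Non Muscle, an enzyme of purine synthesis, fell by 2.93 (SE 0.28). DnaJ Homolog, Subfamily B, Member 11, a chaperone of the endoplasmic reticulum, fell by 2.89 (SE 0.44). The other titles of the 12 largest falls were Dual Specificity Phosphatase 3, Protein Tyrosine Kinase 9-like, Zinc Finger And BTB Domain Containing 41 Homolog and Calcium Regulated Heat Stable Protein 1, with log2 fold changes of -3.49, -3.24, -3.08 and -2.84. Several of these nearshore means lay at 2 to 4 on this scale, below the median of the table, where the distance from background is not known. So did the offshore means of Fibrinogen C Domain Containing 1 (3.48), F-box Protein 32 (2.94), Protocadherin 1 (2.84) and the CYP76C1 title (2.61), so the sizes of these changes are uncertain.

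**Figure D1:**
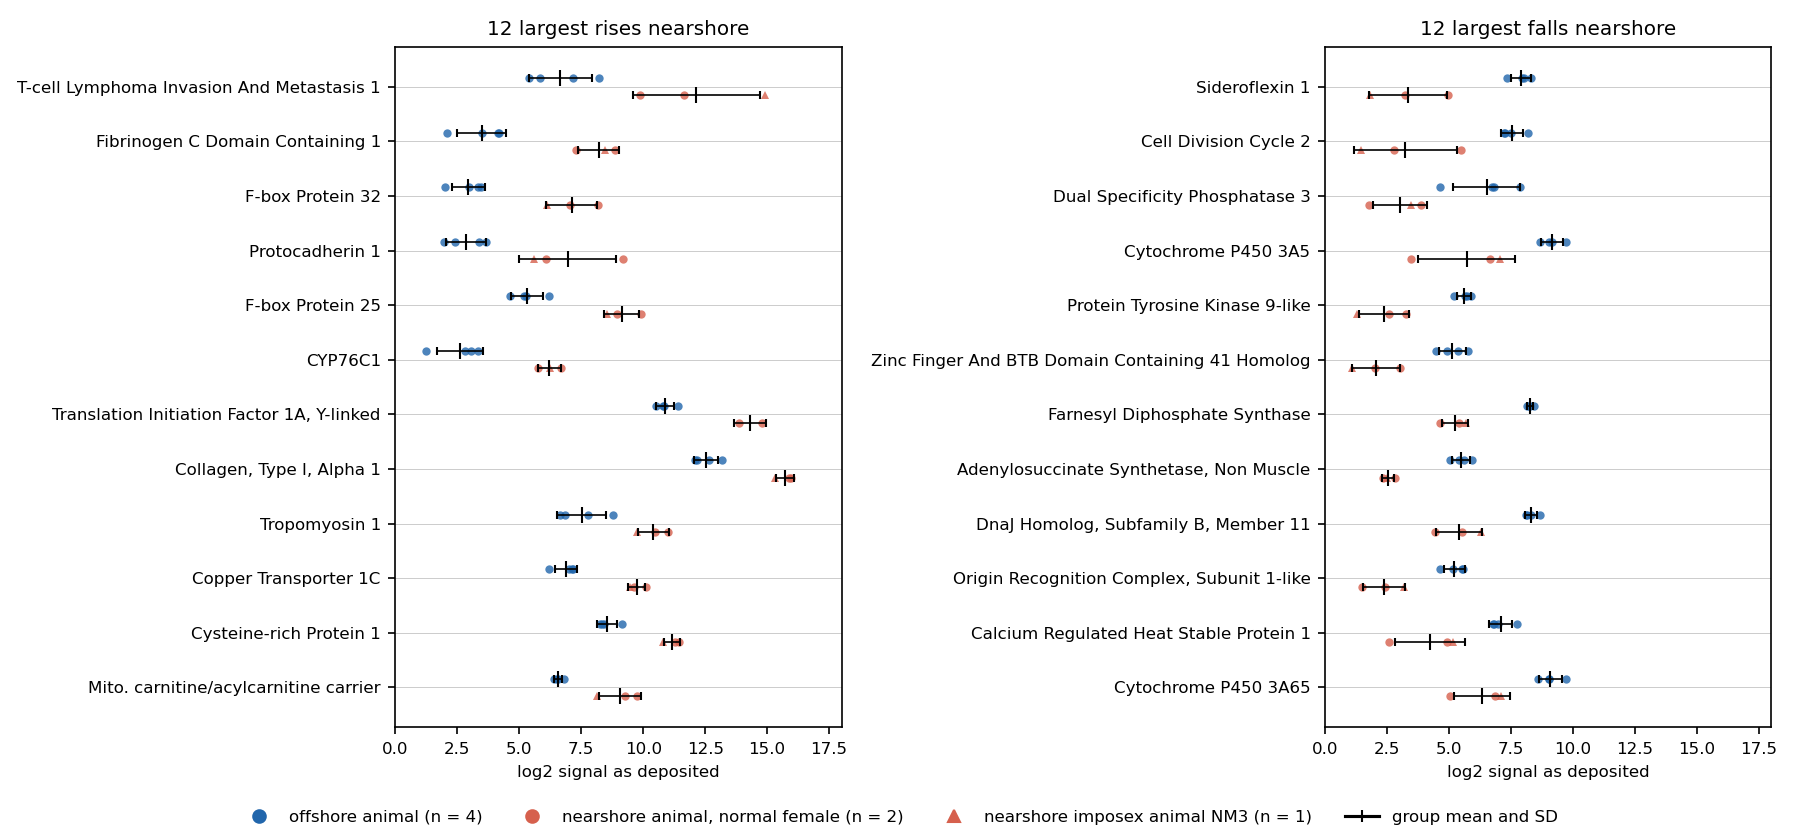
Deposited log2 signal (horizontal axes) of the 12 titles with the largest rises and the 12 with the largest falls nearshore, 1 point per animal, with the group mean and SD in black; NM3 has no point for Translation Initiation Factor 1A. In each of these titles every nearshore point lies on the same side of all 4 offshore points.

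In each of the 400 changed titles the values of the 2 groups did not overlap. Of all titles, 1054 (24.4%) had groups without overlap, against the 5.71% that chance gives for 4 against 3. At an unadjusted p under 0.05 there were 1129 titles, against 216.4 expected by chance. The count of changed titles was sensitive to single animals. It was 302 without the imposex animal NM3 (147 higher, 155 lower), and from 116 to 206 without NF1, NF3, OF1 or OF2. Without OF3 it was 42 and without OF4 it was 34. Of the 24 titles with the largest changes, 23 still passed without NM3, 10 without OF3 and 8 without OF4. Of the 7 fits without 1 array, Dual Specificity Phosphatase 3 passed in 1, Protocadherin 1, Tropomyosin 1, Calcium Regulated Heat Stable Protein 1 and Polypeptide 5 of subfamily 3A in 2, and Polypeptide 65 in 3. The 8 that passed in every alternative were Fibrinogen C Domain Containing 1, F-box Protein 32, F-box Protein 25, Collagen, Type I, Alpha 1, Copper Transporter 1C, Cysteine-rich Protein 1, Farnesyl Diphosphate Synthase and Adenylosuccinate Synthetase, Non Muscle.

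The second comparison asked whether groups of related genes shifted together. None of the 17 gene lists tested passed an adjusted p of 0.05 in camera, 3 had an unadjusted p under 0.05 at the preset correlation, and 0 did with an estimated correlation (fry, 0 adjusted and 6 unadjusted). With stray titles left out, 0 lists passed and 5 had an unadjusted p under 0.05. The descriptions that follow therefore rest on the single titles that passed.

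In the list of oocyte maturation and meiosis, 18 of 24 titles had lower means nearshore and the median log2 fold change was -0.69, but only MAD2 Mitotic Arrest Deficient-like 2 fell, by 1.16 (SE 0.27), and Anaphase Promoting Complex Subunit 13 rose, by 1.46 (SE 0.35). The list's adjusted p was 0.158, and adjusted p = 0.853 with an estimated correlation. Similar To Anaphase Promoting Complex Subunit 5 had a log2 fold change of -1.18 (adjusted p = 0.0675), and PMS2 Postmeiotic Segregation Increased 2, a mismatch repair protein, one of -1.68 (adjusted p = 0.0897). Cell Division Cycle 2 and Cell Division Cycle 25C, the phosphatase that activates it, belong to oocyte maturation by function, but their wording was not in the list's pattern. Cell Division Cycle 25C, looked up after the data were seen, fell by 2.09 (SE 0.41, adjusted p = 0.0288). Leaving out any 1 array kept the list's median between -0.83 and -0.43. Anaphase Promoting Complex Subunit 13 passed in none of these fits, and MAD2 Mitotic Arrest Deficient-like 2 only without OF1.

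The germ cell pattern matched 2 titles, too few for a list test. Piwi-like 1, which guards germ cells against transposons, had a log2 fold change of -1.92 (adjusted p = 0.0580), and Bol, Boule-like, an RNA-binding protein of meiosis, one of 1.34 (adjusted p = 0.0804). Adjusted over the list alone, both passed, with an adjusted p of 0.0105. In the list of egg yolk and egg envelope, 1 of 13 titles rose, Oxidized Low Density Lipoprotein Receptor 1, by 1.60 (SE 0.35). It was matched by the words of its name, which do not make it a yolk receptor. The list's median was 0.41 (adjusted p = 0.706), and the rise passed in 1 of the 7 fits without 1 array. Similar To CUB And Zona Pellucida-like Domains 1 and Similar To Low-density Lipoprotein Receptor-related Protein 1B Precursor had log2 fold changes of 1.29 and 1.43 and did not pass. Vitellogenin 2, the yolk precursor, was looked up after the data were seen. It stood near the top of the scale offshore, at 17.07 ± 0.21, and at 15.36 ± 2.34 nearshore, where NF1 had 12.69, NM3 16.35 and NF3 17.03 (adjusted p = 0.310). Whether the brightest spots were saturated is not known. Of 49 sperm and axoneme titles, 2 rose and 3 fell (list adjusted p = 0.789). The 3 falls were Nuclear Autoantigenic Sperm Protein, a histone chaperone of dividing cells in spite of its name, by 2.23 (SE 0.30), Testis-specific Serine Kinase 1 and Similar To Extraembryonic, Spermatogenesis, Homeobox 1-like. The rises were Similar To T-complex Testis Expressed 1 / Dynein, Light Chain, Tctex-type 1, by 1.20 (SE 0.21), and Testis-specific Kinase 2, looked up after the data were seen, by 2.07. Leaving out 1 array gave 0 to 3 rises and 0 to 3 falls in this list.

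Of the 24 titles of DNA replication and cell cycle, 6 fell and 0 rose. Besides Origin Recognition Complex, Subunit 1-like, these included Replication Factor C 2, 40kDa, part of the complex that loads the replication clamp, which fell by 1.65 (SE 0.30). Replication Protein A3, 14kDa, a subunit of the complex that binds single-stranded DNA, fell by 1.70 (SE 0.31), and MC4 Structural Maintenance Of Chromosomes 4-like 1, a condensin subunit by its name, by 1.88 (SE 0.37). Adjusted over the list alone, 7 fell and 2 rose. Fisher's exact test of the 6 falls gave p = 0.00129, adjusted p = 0.0440 over 34 tests. That test did not match titles on signal level, and dim titles rarely passed. The camera test of the whole list gave an adjusted p of 0.633, and adjusted p = 0.853 with an estimated correlation. The list's median was -0.04. It turned to 0.05 after cyclic loess, and to between 0.01 and 0.11 without NF1, NF3, OF2 or OF3. It was -0.89 once 5 reverse transcriptase titles that the pattern had caught were left out (adjusted p = 0.0858). The number of falls was 4 without NM3 or OF1, 2 without NF3, 1 without OF2 or OF3, and 0 without NF1 or OF4.

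Of 75 cytosolic ribosomal protein titles, 7 fell and 0 rose. Ribosomal Protein S10 fell by 2.56 (SE 0.47), Ribosomal Protein L32 by 1.94 (SE 0.29) and Ribosomal Protein S19 by 1.77 (SE 0.24). A title for the same protein, Similar To 60S Ribosomal Protein L32, fell by 1.40 (SE 0.22). The median over the list was -0.30, and its adjusted p of 0.143 became 0.0137 after quantile normalization, 0.0236 with array weights and 0.00773 without NM3. With an estimated correlation it was adjusted p = 0.853. Relative to the offshore mean, the list's median was -0.34 in NF1, -0.35 in NF3 and -0.14 in NM3. Offshore animals ranged from -0.18 in OF1 to 0.15 in OF3, so NM3 lay within their range. Without OF3 or without OF4, 0 members of the list passed. In the list of oxidative phosphorylation, 8 of 88 titles fell and 2 rose (median -0.23, adjusted p = 0.449). The number of falls was 5 without NM3, 4 without OF1, 3 without OF2, 2 without NF1 or NF3, and 1 without OF3 or OF4. The falls included ATP Synthase, H+ Transporting, Mitochondrial F0 Complex, Subunit G, by 2.46 (SE 0.28), the gamma subunit of the F1 complex, by 1.44 (SE 0.25), and Cytochrome C Oxidase Subunit Vb, by 1.44 (SE 0.25). NADH Dehydrogenase Fe-S Protein 1, 75kDa, a core subunit of complex I, rose by 1.87 (SE 0.30). The other rise was a vacuolar ATPase subunit, which is not part of the respiratory chain.

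Titles of muscle and extracellular matrix mostly had higher means nearshore. In the muscle list, 21 of 29 titles lay above 0, 3 rose and 1 fell (median 0.31, adjusted p = 0.243). Besides Tropomyosin 1, the rises were ENSANGP00000023757 / Myosin Light Chain, by 2.72 (SE 0.58), and Myosin, Heavy Polypeptide 9, Non-muscle, by 1.99 (SE 0.27), a motor protein of non-muscle cells. The title that fell, Adenylosuccinate Synthetase, Non Muscle, is not a muscle protein. The number of rises stayed 3 without NM3, and was 2 without OF2, 1 without NF1, NF3, OF1 or OF4, and 0 without OF3. In the extracellular matrix list, 16 of 21 titles lay above 0, 3 rose and 0 fell (median 0.30, adjusted p = 0.243). Collagen, Type I, Alpha 1, Collagen, Type VI, Alpha 3 and Matrilin 2 rose by 3.20 (SE 0.34), 1.40 (SE 0.22) and 1.83 (SE 0.45). Of the 7 fits without 1 array, they passed in 7, 5 and 0. Of the matrix rises 1 was left without OF3 or OF4 and 2 when any other array was left out, and the list's median ran from 0.06 without NF3 to 0.44 without NF1. Similar To Secreted Nidogen Domain Protein had a log2 fold change of 2.08 (adjusted p = 0.0700). Both lists had adjusted p = 0.853 with an estimated correlation. By animal the sites overlapped. Relative to the offshore mean, the median over both lists without stray titles was 0.41 in NF1, 0.33 in NM3 and 0.26 in NF3. Offshore it was 0.31 in OF1, 0.12 in OF2, -0.09 in OF3 and -0.21 in OF4. Among their titles above the median level of the table, nearshore animals were at 1.02 to 1.35 and offshore animals at -0.43 to 0.47. Beside the muscle and matrix rises stand the lists of oocyte maturation and of DNA replication, whose medians were -0.69 and -0.04. Without stray titles, picked after the matches were seen, the median over both of these was -0.80, against 0.42 over muscle and matrix.

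Markers of other tissues went both ways. In the digestive gland list 2 of 37 titles rose and 2 fell (median -0.02, adjusted p = 0.789). Carboxypeptidase A1, a digestive protease, rose by 1.67 (SE 0.26), and Serine Carboxypeptidase 1, a lysosomal-type protease, fell by 1.83 (SE 0.42). The other changed members, Phospholipase C, Beta 4 (2.24) and Phospholipase D2 (-1.87), act in signalling and were caught by the word lipase. In the haemocyte and immune list 1 of 29 titles rose, Fibrinogen C Domain Containing 1, and 2 fell. Collectin Sub-family Member 11, a lectin of innate immunity and among the brightest titles at 17.07 ± 0.10 offshore, fell by 1.48 (SE 0.24). The list's median was 0.09 (adjusted p = 0.911). In both lists 0 titles fell without OF3 or OF4. The digestive gland rises were then 0 as well, while the haemocyte list kept 1 rise whichever array was left out. The nerve and egg-laying hormone pattern matched 2 titles. Of these, Gonadotropin Inducible Transcription Repressor 1, a zinc finger protein and not a hormone, fell by 2.18 (SE 0.26), and EGg Laying Defective did not pass.

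In xenobiotic metabolism 2 of 56 titles rose and 4 fell (median -0.07, adjusted p = 0.911). Cytochrome P450, Family 1, Subfamily B, Polypeptide 1 and Cytochrome P450, Family 4, Subfamily A, Polypeptide 10 rose by 1.68 (SE 0.34) and 1.38 (SE 0.29), while Similar To Carboxylesterase Family Member, by 1.65 (SE 0.29), and Polypeptides 5 and 65 of subfamily 3A were among those that fell. The 2 titles of subfamily 3A may stand for 1 gene, so they need not be separate falls. A further title of that subfamily, Polypeptide 43, looked up after the data were seen, did not pass. Leaving out OF3 or OF4 left 0 rises and 0 falls in this list, and leaving out OF1 or OF2 left 1 fall. The rises were also 0 without NF1, NF3 or OF2, 1 without OF1 and 2 without NM3. Of the 7 fits without 1 array, the title of Family 1 passed in 1 and that of Family 4 in 2. Among 20 steroid, retinoid and nuclear receptor titles (median -0.06, adjusted p = 0.954), Sulfotransferase Family 1B, Member 1 rose by 1.62 (SE 0.38) and Similar To Nuclear Receptor Coactivator 7 fell by 2.14 (SE 0.52), but 0 titles of this list passed without NF1, NM3 or any offshore array. Hydroxysteroid Dehydrogenase 12 and Sulfotransferase, Estrogen-preferring had log2 fold changes of -1.28 and 1.32 and did not pass. Of 64 stress and antioxidant titles 3 fell and 0 rose (median -0.13, adjusted p = 0.789). Heat Shock 10kDa Protein 1, the mitochondrial co-chaperonin, fell by 1.67 (SE 0.26), Peroxiredoxin 3, a mitochondrial peroxidase, by 1.81 (SE 0.42), and Thioredoxin H-like Protein by 1.84 (SE 0.33). Peroxiredoxin 3 passed in none of the fits without 1 array. The list held 3 falls, not the same 3, and 1 rise without NM3, 2 falls without OF1 or OF2, 1 without NF3, and 0 without NF1, OF3 or OF4.

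Among 31 titles of tubulin and cytoskeletal transport 5 rose and 2 fell (median 0.07, adjusted p = 0.789). Tubulin, Beta 3 rose by 2.27 (SE 0.36) and Kinesin 2 by 1.51 (SE 0.30), whereas Kinesin Family Member 20A, a motor of cell division, fell by 2.30 (SE 0.23) and Cytoplasmic Dynein Light Chain 2 by 2.14 (SE 0.36). The 5 rises became 3 without OF2, 2 without NM3 or OF1, 1 without NF3 or OF3, and 0 without NF1 or OF4, while 1 or 2 titles fell each time. The 23 histone and chromatin titles held 1 rise and 1 fall (median -0.07, adjusted p = 0.784). H2A Histone Family, Member V, a histone variant, fell by 2.08 (SE 0.26). Histone Cell Cycle Regulation Defective Interacting Protein 5, caught by the word histone in the name of a partner, rose by 1.84 (SE 0.37). At least 1 title of this list fell whichever array was left out, and 1 rose only without NM3. Of 79 proteasome and ubiquitin titles 2 rose and 1 fell (median 0.09, adjusted p = 0.633), the rises being Ariadne Ubiquitin-conjugating Enzyme E2 Binding Protein Homolog 1, by 1.34 (SE 0.22), and Proteasome 26S Subunit, Non-ATPase, 11, by 1.38 (SE 0.27). Here 4 titles rose and 0 fell without NM3, 1 rose and 0 fell without NF3, OF1 or OF2, and 0 passed without NF1, OF3 or OF4. Of 38 lysosome and cell death titles 1 fell, Programmed Cell Death 2, by 1.57 (SE 0.38), and 1 fell only without NM3 or OF1. Caspase 3, Apoptosis-related Cysteine Protease had a log2 fold change of 1.12 (adjusted p = 0.0519), and the list's median was 0.42 (adjusted p = 0.449). For xenobiotic metabolism, digestive gland and haemocytes the direction of the camera test, the median and the mean did not all have the same sign.

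**Figure D2:**
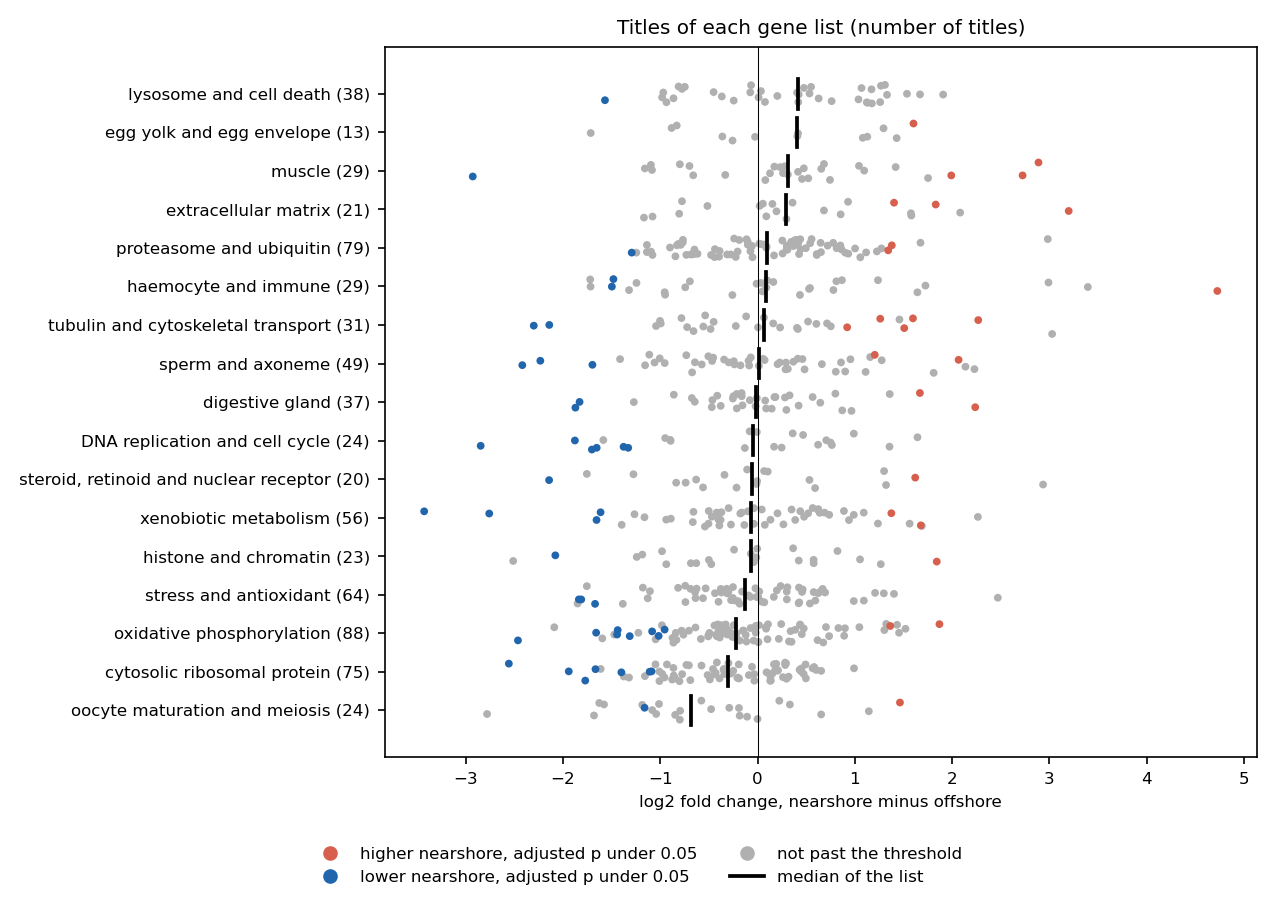
Log2 fold change, nearshore minus offshore (horizontal axis), of each title in the 17 gene lists tested, with the number of titles in brackets, ordered by the list's median (black bar); red and blue points passed an adjusted p of 0.05 upward and downward, grey points did not. The vertical scatter within a list only separates the points. The list medians run from -0.69 for oocyte maturation and meiosis to 0.42 for lysosome and cell death, and most titles in each list did not pass.

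The third comparison asked whether the whole profiles of the 2 sites differed. Pearson's correlation across titles was 0.965 on average between offshore arrays (0.954 to 0.974), 0.948 between nearshore arrays (0.937 to 0.958) and 0.939 between sites (0.913 to 0.948). Distances between sites exceeded distances within sites by 17.04 on average. Of the 35 splits of the arrays, the real one alone gave a value this large, and the highest other split gave 8.23 (exact permutation p = 0.0286, the smallest the design allows). The first principal component, with 36.7% of the variance, separated the sites. The second, with 21.7%, spread the nearshore animals, with NM3 at 36.8, NF1 at -21.9 and NF3 at -40.5. The offshore animals lay at -11.7 to 19.8 on it.

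**Figure D3:**
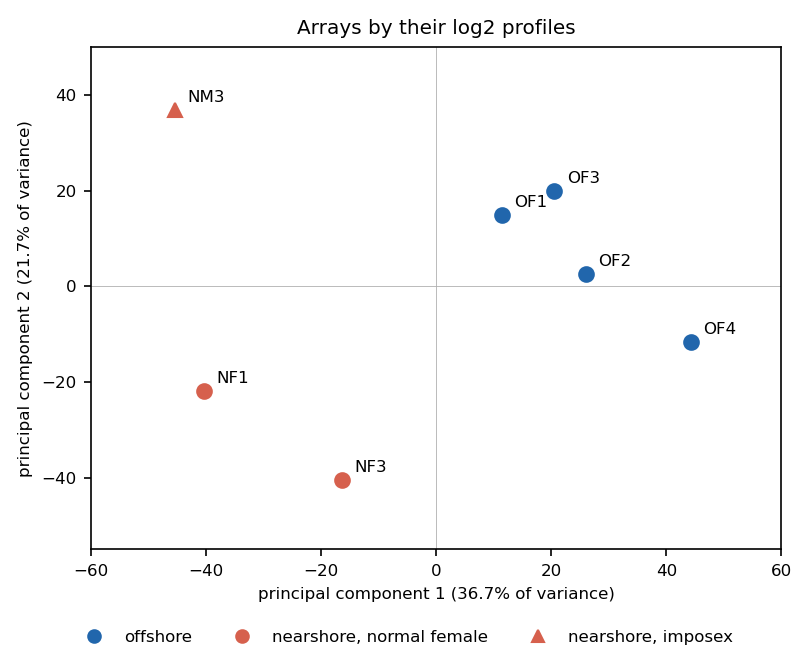
The 7 arrays on the first and second principal components of the log2 values of 4275 titles, 1 point per animal, with the share of variance on each axis. The offshore animals lie at 11.4 to 44.3 on the first component and the nearshore animals at -45.5 to -16.4.

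The imposex animal is 1 animal, so its values have no replicate and no test. NM3 lay at least 4-fold above both other nearshore animals in 115 titles and at least 4-fold below both in 64, of 4282 titles with all nearshore values. The same counts were 70 and 24 for NF1 and 43 and 75 for NF3. Among named titles, chosen after their values were seen as the farthest in each direction, Amidase was at 7.53 in NM3 against 2.47 in NF1 and 2.51 in NF3. Offshore animals had Amidase at 2.69 to 5.07. Cytochrome C Oxidase Subunit II was at 2.01 in NM3 and between 8.22 and 10.52 in the other 6 arrays, and EF-hand Calcium Binding Domain 2 was at 2.35 against 8.14 to 9.36. Both are among 5 titles in which NM3 alone was below 4 while the other 6 arrays were above 8. NM3 also lacked values for 45 titles, whose median level was 11.14, and had the lowest array weight, 0.523. Whether these lows come from the animal or from its array is not known. Low-density Lipoprotein Receptor Related was at 17.16 in NM3, and at 12.72 in NF1 and 9.63 in NF3, but it also ranged from 7.87 to 16.43 among the offshore animals.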

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

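Of the tests in this part, the count of titles over other splits of the animals and the trend with signal were planned. The tests of the lists over splits, of mitochondrial ribosomal proteins and of tissue sets were chosen after the results were seen. Among the named titles and 2 array summaries, 92 sets of 4 offshore values were searched for 1 value far from the others. The ratio of the gap to the range passed the 95% limit of Dixon's test in 5 of them, where chance alone gives about 4.6. Cysteine-rich Protein 1 was at 9.16 in OF4 and at 8.27 to 8.41 in the others (ratio 0.844). PMS2 Postmeiotic Segregation Increased 2 was at 4.48 in OF1 and 3.75 to 3.88 in the others (0.833). Similar To 60S Ribosomal Protein L32 was at 14.52 in OF1 and 14.81 to 14.85 in the others (0.881). ENSANGP00000023757 / Myosin Light Chain was at 4.93 in OF4 and 6.54 to 6.76 in the others (0.882). Tumor Necrosis Factor Receptor Superfamily, Member 11b was at 3.20 in OF4 and 2.30 to 2.33 in the others (0.961).

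The titles changed between the sites were set against all 35 ways of splitting the 7 animals into 4 and 3. Only 1 split, the real one, gave 400 or more titles. The highest other split gave 25, which argues against chance in how these animals fell into groups as the whole cause. The test cannot exclude chance, since 1 of 35 (0.0286) is the smallest share it can give. A normalization that treats bright and dim titles differently was tested through the median log2 fold change in 10 bins of signal. Its largest size was 0.15, far below the smallest change called, 0.92, which argues against such a trend. A difference between the sites other than reproduction, or in how the 2 collections were handled, stays open and untested, since each group came from 1 place.

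The counts of gene lists give no such separation. In 16 of the 35 splits at least 3 lists had an unadjusted p under 0.05 in camera, as in the real split, and the highest other split had 7, so chance cannot be excluded for the number of shifted lists.

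Without stray titles, which were picked by name after the matches were seen, 7 of 42 oocyte and replication titles fell and 1 rose, and 5 of 39 muscle and matrix titles rose and 0 fell. With them the muscle list held 3 rises and 1 fall. The others did not pass, and none of the 4 lists passed in camera. The mean log2 fold change of the latter exceeded that of the former by 1.19. A split of the animals by chance stays open, since 2 of the 35 splits gave a difference as large, the highest other one being 1.19 as well. A larger share of other tissue in the nearshore samples may also contribute. More of every other tissue would raise digestive gland and haemocyte titles along with muscle and matrix, and only this case was tested. More muscle or connective tissue alone need not raise them, so the test does not bear on that case. A first form of this test used all titles of these lists and gave a difference in medians of 0.37 (bootstrap interval 0.10 to 0.84). That outcome would have been read as against more of every other tissue. The bootstrap drew titles and not animals, so its intervals leave out the spread between animals. The first form was replaced after its outcome was seen, because digestive gland and haemocyte titles lie near the lower end of the scale (median level 3.03). Among titles above the median level, 15 digestive gland and haemocyte titles had a median of 0.05 and 17 muscle and matrix titles one of 1.04, but the bootstrap interval of the difference ran from -0.27 to 2.74, so that a share of other tissue and a change within the ovary cannot be told apart here. The impaired reproduction that the labels give for the nearshore site was not tested as an explanation.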

How the results depend on the processing

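Cyclic loess and the lists without stray titles were chosen after the data were seen. The offset and pseudocount alternatives for linear intensities were not run, since the table is on a log scale. The 400 changed titles (169 higher, 231 lower) became 384 to 448 under quantile normalization, median centring, the dim filter, array weights, cyclic loess, both other priors and averaging of names, with 347 to 397 of them shared. A limit of 1.5-fold removed none, since every change called was larger. The ordinary pooled-variance test gave 143 (61 higher, 82 lower), with 135 shared. At an adjusted p under 0.10 there were 659 (284 and 375). Leaving out 1 array gave 34 (without OF4) to 302 (without NM3) titles, 14 to 147 higher and 20 to 155 lower. Fewer arrays lower the power of the test, but why OF3 and OF4 count most was not tested. Both have the highest array weights, 2.06 and 1.31, and NM3 the lowest, 0.523.

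The number of lists past the threshold was 1 instead of 0 under quantile normalization, with array weights and without NM3, each time the cytosolic ribosomal proteins; leaving out single arrays gave 0 to 1. The median of that list lay within the offshore range in NM3, and array weights gave NM3 the least weight. The cause of these shifts was not tested. The number of lists past the threshold was 0 under the other alternatives. In 11 of 255 list values the direction of the test changed, none of them past the threshold. The separation of the groups was 17.16 after quantile normalization, 18.03 with the dim filter and 0.0221 as a rank-based distance, each with an exact permutation p of 0.0286. Leaving out 1 array gave 12.6 to 22.6, and the real split was each time the highest of the 15 or 10 possible. Of 1616 values of the 90 named titles under alternatives, 1292 stayed on their side of the threshold, 291 lost and 33 gained the call. No paired analysis was possible because the animal codes name single animals and pair none across sites. Signal over background is not known.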

Other observations

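Other groups of titles were put together by name after the per-title results were seen, so their counts describe these data and test nothing. Of 5 titles for the Arp2/3 complex, which branches actin filaments, 3 rose and 0 fell, among them Actin Related Protein 2/3 Complex, Subunit 3, by 1.77 (SE 0.27, adjusted p = 0.0173). The other rises, by 1.55 and 1.37, were titles that both name Subunit 2 and may stand for 1 gene. Titles of Subunits 4 and 1A, at -0.39 and 0.27, did not pass. Of 5 sarcomere titles outside the muscle list 4 rose, including KETtiN Homolog by 1.64, Nebulin by 1.22 and Myopalladin by 1.43. The title that did not pass, Similar To BMKETTIN, also names kettin and had a log2 fold change of 0.41. Of 12 titles for folding and retention in the endoplasmic reticulum 4 fell and 0 rose. Endoplasmic Reticulum Protein 29 fell by 2.22 (SE 0.47), Protein Disulfide Isomerase Associated 4 by 1.84 (SE 0.40) and Protein Disulfide Isomerase-related Protein by 1.71 (SE 0.29), while Protein Disulfide Isomerase Family A, Member 3 had a log2 fold change of 0.12. The remaining fall, Similar To Endoplasmic Reticulum Protein 29 Precursor, by 1.62, may stand for the same gene as Endoplasmic Reticulum Protein 29. Of 9 titles for cell division cycle proteins and thymidine kinases 4 fell and 0 rose, and Thymidine Kinase 1, Soluble, which supplies thymidine nucleotides in dividing cells, fell by 2.03 (SE 0.40). In isoprenoid synthesis Farnesyl Diphosphate Synthase and Phosphomevalonate Kinase fell, by 3.02 and 1.62, and Isopentenyl-diphosphate Delta Isomerase 1 rose by 1.16, of 6 titles.

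Of 34 titles for mitochondrial ribosomal proteins, which were not among the lists fixed before the data were examined, 9 fell and 2 rose. The share that fell, 26.5%, compares with 5.34% of all titles (Fisher's exact test, two-sided p = 4.88e-05, for a set chosen after its falls were noticed). All titles include dim ones, which rarely passed. Of 10 bins by signal, the dimmest held 0 falls among 432 titles, and each of bins 6 to 10 held 29 to 45 among 432 or 433. The dimmest of the 34 titles, L19, stood at percentile 57.9 of level, so 5.34% is too low a baseline for them. Mitochondrial Ribosomal Protein S34 fell by 1.94 (SE 0.24), L19 by 1.73 (SE 0.39) and L41 by 1.57 (SE 0.32), while Mitochondrial Ribosomal Protein L1 rose by 1.26 (SE 0.29) and L21 by 1.24 (SE 0.29). The median log2 fold change was -0.71. Both tests below were chosen after this was seen.

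Against random lists matched on signal, the median lay at the 0.1 percentile of 10000 such lists, whose central 95% ran from -0.47 to 0.40. The set was chosen for its falls, so a low place among random lists was likely in advance. Random lists also ignore correlation between the members. Brightness as the cause is argued against by the planned bins of signal given above. Their median log2 fold changes had a largest size of 0.15. A chance split of the animals stays open. Only 1 of the 35 splits gave a mean difference as large, -0.56 relative to all titles, but the highest other split reached 0.54, and with adjustment over 18 lists, added after the share of splits was seen, the p was 0.171, so that 35 splits are too few to decide. The camera p was 8.74e-05 at the preset correlation and 0.101 with an estimated one. The number of falls dropped to 4 without NM3 or NF1, 3 without NF3, 2 without OF1 or OF2 and 1 without OF3 or OF4, while the median stayed between -0.84 and -0.65.

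Array NM3 also stood apart in single bright titles. In 5 titles NM3 was below 4 while the other 6 arrays were all above 8. The same count was 1 for OF1 and for OF2, and 0 for NF1, NF3, OF3 and OF4. Estrogen Receptor 1, looked up after the data were seen, was at 2.60 ± 0.97 nearshore and 1.30 ± 0.41 offshore, near the lower end of the scale, with a log2 fold change of 1.30 (SE 0.47, adjusted p = 0.134).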
